A study of Saccharomyces cerevisiae with 32 samples.

How the data were processed

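The series holds 32 libraries from 8 natural isolates of Saccharomyces cerevisiae: 2 RNA-seq libraries and 2 ribosome profiling libraries per isolate. Per the labels' protocols, ribosome footprints were made by RNase I digestion of cells collected by filtration, with ribosomal RNA removed by hybridisation, and the RNA-seq libraries came from a strand-preserving kit. The authors deposited, for each library, a table of whole-number read counts per open reading frame, not normalized. Per the submitters' processing notes, CASAVA 1.8 and STAR 2.7.0a were used with the genome build sacCer3. The counting tool, its annotation, its treatment of strand and of reads that match several genes, and the trimming of footprints are not given in the sources used here. Near-identical copies, overlapping genes and antisense genes are therefore uncertain, since their reads could have been split or assigned to one another. A second value deposited in each table equals the number of coding codons less 10 for 94.5% of the open reading frames with a gene record (5675), and was used only as coding length.

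The tables list 6696 open reading frames. Of these, 6008 matched the gene table of the R64 assembly by locus tag, which sacCer3 denotes, and 5276 had a symbol; the 688 without a match hold 0.379% of the reads. Coordinates are those of that assembly, counted from 1. The tables include 28 mitochondrial open reading frames, whose share of reads is reported, and 4 of the 2-micron plasmid, with 0 reads. The labels do not say that the replicates were separate cultures, so p-values measure the spread between these samples, which may be partly technical. Replicate pairs were compared by a chi-square test over genes: chi-square per degree of freedom was 2.14 to 31.4, so no pair was a repeated library.

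Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes passed edgeR's filter on low counts (minimum count 10, isolate as group), libraries were scaled by TMM within each assay, and edgeR's quasi-likelihood F-test was used with Benjamini-Hochberg adjustment at 0.05. A test over all 8 isolates, contrasts of each isolate against the mean of the other 7 on the log2 scale, and all 28 pairs were made for mRNA (6269 genes), for footprints (5347) and for TE (5337). TE was tested as the interaction of assay and isolate in 1 model over all 32 libraries. CPM (read counts scaled to equal library totals) use the reads on all open reading frames.

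The slope of footprint on mRNA differences used log2 CPM (prior count 2) centred per library and expressed as deviations from the mean of the 8 isolates. Products were taken across different replicates, to limit the effect of counting noise; the SE came from a jackknife over isolates, and the ratio of variances was tested by an exact two-sided permutation over 256 swaps of the assays within isolates. A gene called in mRNA and TE was classed by the sign of the covariance of its TE and mRNA deviations. In all, 58 gene lists were fixed with 1463 names, of which 1456 matched, covering 1436 distinct genes. Lists with at least 5 members were tested with limma's camera (preset correlation 0.01, and again with an estimated correlation), adjusted over 448 combinations of list and isolate within a layer. List slopes were set against 10000 random lists of the same size matched on mRNA level, for lists of at least 8 members. The samples, tests, gene lists, alternatives of the first plan and rules for naming genes were set before the data were examined; the alternatives with thinned mRNA libraries, a common prior of 2 CPM, a length correction, and fewer isolates were chosen after seeing the data.

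The genes named are those that a fixed rule picked: per isolate, the 3 largest called changes in mRNA and in TE with both libraries beyond the 14 others, a symbol, and enough reads. Enough meant a mean of 5 CPM and more than 3 reads for mRNA, and a mean of 20 reads per library in both assays for TE. Also named are the 8 most variable genes with TE against mRNA and with it, the 5 highest and 5 lowest in mean TE, and up to 4 members of each list described, by size of change. The rule adds up to 3 genes without reads per isolate, and GCN4, HO, CUP1-1, ENA1, GAP1 and PHO84. RIC1, ALG6 and the genes listed with them as called in opposite directions, and FRE5 and FIT3 in BPL, were named after their values were seen. Where an isolate had 0 reads on a gene, the fold is a bound against a floor of 3 reads over its 2 libraries of that assay; intervals are exact Poisson or Clopper-Pearson at 95%, and intervals and floors cover counting error only.

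Each step was tested on simulated counts drawn from the real means and depths, with 200 changed genes. For BPL against the others, 94% of genes changed by 1 on the log2 scale were called in mRNA (6089 genes), 57.1% in footprints (5177) and 51.5% in TE (5180), and 5.37%, 4.79% and 2.04% of calls fell on unchanged genes. For BAN, 93% were called in mRNA (6101 genes), 8.6% in footprints (5170) and 8.16% in TE (5182) at that size, and 100%, 40% and 37.1% at a change of 2. In the test over all 8 isolates, 6.95%, 8.89% and 4.5% of calls fell on unchanged genes with BPL changed, and 17.6% in footprints with BAN changed. Slopes simulated at 1, 0.6 and 0 over 5337 genes came out at 0.928, 0.579 and 0.00279. A slope of 1 gave 0.965 over 1212 genes with a mean of at least 100 reads per library in both assays. A list simulated at 0 was found (adjusted p = 0.011, permutation), with 3 of the other lists also past the threshold, so single list slopes carry a higher error than their p states. Alternatives covered scaling, the filter, DESeq2, limma voom with library weights, a replicate block, each library left out, prior counts of 0.5 and 10, and other read minimums. No sample was left out, and the genome sequence was not used here.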

Results

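Messenger RNA and ribosome-protected mRNA fragments (footprints) were counted in 8 natural isolates of budding yeast, named AMH, BAN, BED, BPL, BTT, CMP, CPI and CQC, all grown in synthetic complete medium. Each isolate had 2 mRNA libraries and 2 footprint libraries, 32 in all. The series asks how far differences in mRNA level between genetic backgrounds are carried through to translation, so every gene was compared at the mRNA level, at the footprint level, and in the ratio of footprints to mRNA, called translation efficiency (TE).

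The mRNA libraries held 3703931 to 11570247 reads on 6696 open reading frames, with a median of 8871574. The first and second mRNA libraries held 6904248 and 10569485 reads in AMH, 4100236 and 3703931 in BAN, 7877545 and 10628892 in BED, and 10153458 and 9893144 in BPL. They held 9865603 and 10124910 reads in BTT, 6128168 and 5783279 in CMP, 10622201 and 11570247 in CPI, and 7005423 and 6181057 in CQC. The footprint libraries were shallower and less even, with a 159-fold range against 3.12-fold in mRNA. The footprint pairs held 349307 and 1134437 reads in AMH, 63336 and 27621 in BAN, 759377 and 1086744 in BED, and 640072 and 1020597 in BPL. They held 3133049 and 4391002 reads in BTT, 145164 and 99809 in CMP, 1424593 and 1424639 in CPI, and 249004 and 275549 in CQC. Over 1362 genes with a mean of at least 100 reads per library in both assays, the replicates of an isolate correlated across genes with r from 0.971 to 0.997 in mRNA. In footprints r was 0.931 to 0.99, except in BAN, where it was 0.797. These are called the genes with at least 100 reads below, but the mean is over all 16 libraries of an assay. The BAN footprint libraries, with 63336 and 27621 reads in all, cannot hold 100 reads on each of them.

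**Figure D1:**
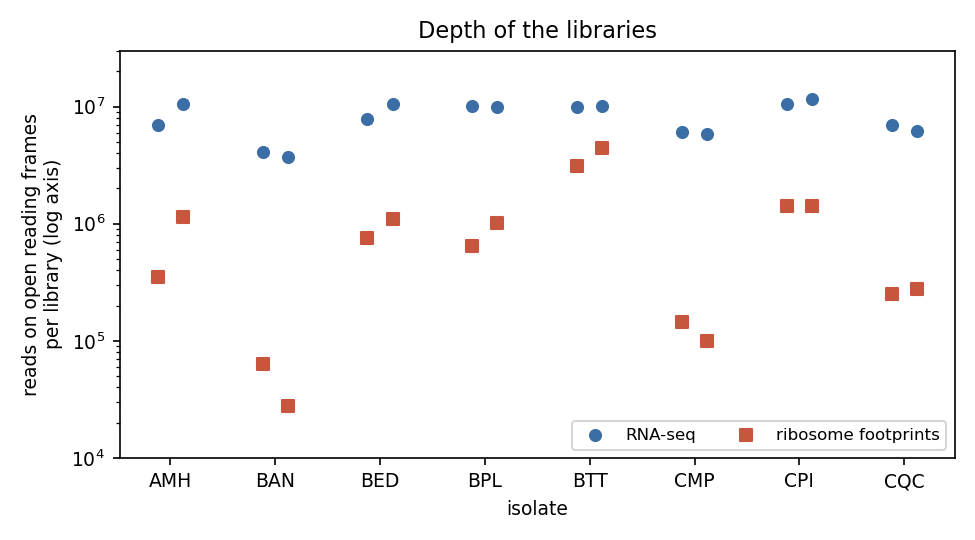
Total reads on open reading frames in each of the 32 libraries (log axis), by isolate, with mRNA and footprint libraries as separate points. The mRNA libraries lie between 3703931 and 11570247 reads, and the footprint libraries reach down to 27621 in BAN.

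The first question was how many mRNAs differ among the isolates. HXT13 (YEL069C), a member of the hexose transporter family, had a mean of 7660 ± 790 CPM in CMP and 0.663 ± 0.14 CPM in BED (SD, n = 2 libraries each). ENO2 (YHR174W), the enolase of glycolysis, stood at 8.71 CPM in CQC against a mean of 4630 CPM in the other 7 isolates. ENA1, a sodium efflux pump, stood at 2420 CPM in CQC against 85.3 CPM in the others. In the omnibus test, 5998 of 6269 genes (95.7%) differed in mRNA, and 5453 of them spanned at least 1 on the log2 scale between the lowest and the highest isolate. For single pairs of isolates, a median of 3756 genes was called, from 1781 between BPL and CPI to 4693 between BED and CQC. These counts come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, as do all counts of called genes here.

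In AMH the genes of cytosolic ribosomal proteins, sulfur assimilation and glycolysis had higher mRNA than in the mean of the other 7 isolates, and genes of the general stress response had lower mRNA. Of 137 cytosolic ribosomal protein genes, 133 were higher and 4 were not called, with a median log2 fold change of 1.41. The largest rises were in RPL13B (2.29 ± 0.090, SE, 2 libraries against 14), RPL16B and RPS14B. Of 27 genes of sulfur amino acid synthesis, 21 were higher and 2 lower (median 1.64). They were led by the sulfate permease SUL2 (4.10 ± 0.10), the sulfhydrylase MET17 (3.31 ± 0.10) and the ATP sulfurylase MET3 (3.22 ± 0.12). Of 25 glycolysis and fermentation genes, 19 were higher and 5 lower (median 1.68). Of these, ENO2 (3.26 ± 0.12), TDH3 (2.79 ± 0.12) and PGK1 (2.62 ± 0.10) rose, while PDC6, a minor pyruvate decarboxylase, fell (-3.47 ± 0.43). Of 32 general stress genes, 26 were lower and 4 higher (median -1.89), led by the hydrophilin SIP18 (-4.63 ± 0.30), DDR2 (-3.28 ± 0.40) and the membrane chaperone HSP12 (-3.10 ± 0.24). In footprints 134 ribosomal protein genes were higher (median 1.17), as were 20 of 25 sulfur genes (median 1.36; 1 was lower) and 16 of 25 glycolysis genes (median 0.90; 2 were lower), and 24 stress genes were lower and 1 higher (median -1.31). TE fell for 16 glycolysis genes and rose for 2 (median -0.76; the same adjusted over the list alone). It fell for 29 ribosomal protein genes and rose for 3 (median -0.33; 38 and 4 adjusted over the list alone). Camera with Benjamini-Hochberg adjustment gave adjusted p = 2.4e-07 and 6.2e-05 for the TE of these lists, and adjusted p = 0.94 for each with an estimated correlation. JEN1 (YKL217W), a lactate transporter, fell most among the genes named by rule (-6.45 ± 0.27; 3.28 against 420 CPM; edgeR with Benjamini-Hochberg adjusted p = 1.5e-10). REE1 (YJL217W) and its neighbour, the isomaltase gene IMA5 (YJL216C), stood far above the others, REE1 at 116 ± 9.1 CPM (SD, n = 2) against 0.94 and IMA5 with a log2 fold change of 6.46 ± 0.26. Adjusted over the list alone, the mRNA counts for ribosomal proteins, sulfur, glycolysis and stress genes were 133 higher, 21 higher and 2 lower, 19 higher and 5 lower, and 4 higher and 26 lower. Adjusted p by camera with Benjamini-Hochberg adjustment was 2.5e-28, 7.5e-07, 8.7e-05 and 7.1e-06 for these mRNA lists in that order, and adjusted p = 0.46, 0.29, 0.49 and 0.55 with an estimated correlation.

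In BAN the genes of heat shock chaperones and of the respiratory chain had higher mRNA, and those of ergosterol synthesis and of cell wall mannoproteins lower mRNA, and the differences of these 4 lists were smaller or less often called in footprints. Fewer calls alone do not show a smaller difference. In counts simulated for BAN, 8.6% of genes changed by 1 on the log2 scale were called in footprints and 93% in mRNA. Of 25 heat shock genes, 22 were higher and 2 lower (median 2.09), led by the aggregate-sorting factor BTN2 (7.12 ± 0.14), the exchange factor FES1 (4.94 ± 0.12), the disaggregase HSP104 (4.27 ± 0.15) and the Hsp40 SIS1 (3.48 ± 0.10). In footprints 6 of them were higher and 19 were not called (median 0.52). In footprints BTN2 stood at 4.97 ± 0.30 and HSP104 at 1.35 ± 0.20. TE fell for 18 and was not called for 7 (median -1.78). Of 41 genes of the respiratory chain and ATP synthase, 39 were higher and 1 lower in mRNA (median 1.72; CYC7 4.39 ± 0.16, QCR10 3.27 ± 0.15). In footprints 10 were higher (median 0.30), and TE fell for 33 and rose for 1 (median -1.40). With each library's trend with coding length removed, the median was 0.67 in footprints and -0.88 in TE, which then fell for 22. Of 26 ergosterol genes, 24 were lower and 1 higher in mRNA (median -1.67; the sterol methyltransferase ERG6 -3.51 ± 0.14, ERG24 -2.68 ± 0.15, ERG11 -2.35 ± 0.12). Of these, 2 were lower in footprints, and TE rose for 14 (median 1.13). Of 29 cell wall genes, 24 were lower and 2 higher in mRNA (median -1.81; DAN1 -3.83 ± 0.26, CIS3 -3.64 ± 0.25, CWP2 -3.40 ± 0.32). In footprints 5 were lower and 2 higher. A pair of sugar lists was higher in BAN mRNA and in footprints. Of the genes of maltose, galactose and sucrose use, with copies that could share reads, 18 of 20 were higher in mRNA (median 2.52) and 8 of 18 in footprints (median 2.39; 18 and 10 adjusted over the list alone). Camera with Benjamini-Hochberg adjustment gave adjusted p = 5.3e-07 and 3e-15, and adjusted p = 0.35 and 0.04 with an estimated correlation, so that the footprint call stood. Hexose transporter genes, with similar copies, were higher for 12 of 19 and lower for 4 in mRNA (median 2.66), and higher for 9 of 18 and lower for 1 in footprints (median 1.43; 11 and 1 adjusted over the list alone, and in mRNA 12 and 4). Camera with Benjamini-Hochberg adjustment gave adjusted p = 0.0018 and 2.2e-12, and adjusted p = 0.46 and 0.086 with an estimated correlation. Adjusted over the list alone, the mRNA counts were unaltered for the first 4 lists, while 10 heat shock and 16 respiratory genes were higher in footprints. By camera with Benjamini-Hochberg adjustment, adjusted p was 3.9e-10, 8.6e-16, 5.6e-11 and 3.6e-06 for the mRNA of the first 4 lists in the order given, and adjusted p = 0.45, 0.45, 0.34 and 0.29 with an estimated correlation. Adjusted over the list alone, TE fell for 20 heat shock genes and 39 respiratory genes (1 rose) and rose for 16 ergosterol genes (1 fell). Camera with Benjamini-Hochberg adjustment gave adjusted p = 3.7e-14, 3.1e-17 and 4.3e-07 for the TE of these 3 lists, and adjusted p = 0.94 for each with an estimated correlation, so that none of these TE calls stood. The mitochondrial genome's own open reading frames took 11.9% ± 0.038 of the BAN mRNA reads (SD, n = 2), beside 1.34% ± 0.24 in AMH, the lowest isolate. BDS1, a sulfatase gene (8.37 ± 0.34), and IMA3 (7.03 ± 0.15), an isomaltase with near-identical copies whose reads could have been split between them, were the other genes named by rule.

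In BED the respiratory chain was lower throughout and glycolysis and ergosterol synthesis were higher. All 41 genes of the respiratory chain and ATP synthase fell in mRNA (median -1.64), led by the cytochrome c isoform CYC7 (-4.24 ± 0.32), QCR10 (-2.76 ± 0.25) and the NADH dehydrogenase NDE1 (-2.68 ± 0.21). Of these, 40 fell in footprints (median -1.30). Mitochondrial open reading frames took 1.67% of the BED mRNA reads. Of 25 glycolysis genes, 18 were higher and 5 lower in mRNA (median 1.60; ENO2 2.73 ± 0.12, the hexokinase HXK2 2.45 ± 0.087, GPM1 2.44 ± 0.097). Of these, 20 were higher and 2 lower in footprints (median 1.23). Of 26 ergosterol genes, 23 were higher and 2 lower in mRNA (median 1.28; ERG27 2.08 ± 0.095, ERG20 2.01 ± 0.087), and 22 were higher in footprints (median 0.91). Of 22 genes under nitrogen catabolite repression, 18 were lower and 1 higher in mRNA (median -1.26), among them the oligopeptide transporter OPT2 (-5.42 ± 0.43), the proline oxidase PUT1 (-2.97 ± 0.25) and the peptide transporter PTR2 (-2.56 ± 0.18). The mRNA counts were the same adjusted over the list alone. Adjusted p by camera with Benjamini-Hochberg adjustment was 1.6e-17, 0.00011, 7.6e-08 and 6.7e-05 for the mRNA of the 4 lists in the order given, and adjusted p = 0.45, 0.49, 0.39 and 0.25 with an estimated correlation. For respiratory footprints camera gave adjusted p = 5.7e-28, and adjusted p = 0.04 with an estimated correlation. The glycolysis and ergosterol lists did not pass the threshold in footprints with an estimated correlation. The transporter genes HXT13 (-7.65 ± 0.33) and HXT17 (-8.41 ± 0.46) and the mitochondrial intron gene AI5_BETA (-9.03 ± 0.52) fell most among the genes named by rule, and reads of the HXT copies could have been split between them.

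In BPL the biotin genes were lower and the sulfur genes higher. All 6 biotin genes fell in mRNA (median -2.54), led by the biotin precursor transporter BIO5 (-4.14 ± 0.18) and the biotin transporter VHT1 (-2.96 ± 0.16), and all 6 fell in footprints (median -2.52; BIO5 -3.88 ± 0.24). Of 27 sulfur amino acid genes, 17 were higher and 3 lower in mRNA (median 1.15; MET3 2.75 ± 0.12, MET2 2.74 ± 0.10, SUL2 2.72 ± 0.10), and 14 of 25 were higher in footprints (median 1.14). IMD2 (YHR216W), the IMP dehydrogenase of guanine nucleotide synthesis, rose to 497 CPM against 17.6 CPM (5.39 ± 0.25, edgeR with Benjamini-Hochberg adjusted p = 6.78e-10) and rose in footprints by 3.82 ± 0.14. Of 24 seripauperin genes, near-identical subtelomeric copies whose counts could hold each other's reads, 17 were counted higher and 4 lower (median 3.49; PAU9 5.69 ± 0.26, PAU20 5.26 ± 0.22). Adjusted over the list alone, 5 rather than 3 sulfur genes and 5 rather than 4 seripauperin genes were lower in mRNA, and the biotin count was unaltered. By camera with Benjamini-Hochberg adjustment, adjusted p was 2e-07 for biotin, 0.00015 for sulfur and 2.5e-05 for seripauperins in mRNA, and adjusted p = 0.29, 0.35 and 0.56 with an estimated correlation.

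In BTT lysine synthesis was higher, and stress genes and flocculins were lower. Of 8 lysine genes, 7 rose and 1 fell in mRNA (median 2.47), led by LYS9 (3.36 ± 0.094), the homocitrate synthases LYS20 (3.30 ± 0.11) and LYS21 (2.60 ± 0.10). Again 7 rose in footprints (median 2.23; LYS9 3.05 ± 0.14). Of 32 general stress genes, 23 were lower and 1 higher in mRNA (median -1.20; GRE1 -5.95 ± 0.31, HSP12 -5.30 ± 0.28, SIP18 -5.08 ± 0.30), and 21 were lower and 4 higher in footprints (median -1.03). FLO11, a flocculin needed for cell-surface adhesion, fell in mRNA (-5.54 ± 0.33) and in footprints (-6.58 ± 0.55), and 4 of 8 flocculin genes were lower in mRNA (median -2.41), of which FLO1, FLO5 and FLO9 could share reads. All 24 seripauperin genes were counted higher in mRNA (median 2.34; PAU21 6.30 ± 0.26, PAU22 6.30 ± 0.25), with the same uncertainty from near-identical copies. The mRNA counts of these 4 lists were the same adjusted over the list alone. Adjusted p by camera with Benjamini-Hochberg adjustment was 1.6e-05 for lysine, 1.7e-09 for stress, 0.011 for flocculins and 4.4e-08 for seripauperins, and adjusted p = 0.29, 0.47, 0.53 and 0.49 with an estimated correlation.

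In CMP thiamine, zinc and respiratory genes were higher and ergosterol synthesis was lower. Of 22 thiamine and vitamin B6 genes, 19 rose in mRNA and 3 were not called (median 1.67), led by the thiazole synthase THI4 (5.90 ± 0.16) and by THI5 (5.03 ± 0.22), one of 4 near-identical copies whose reads could have been split. In footprints 16 rose (median 1.77). Of 14 copper and zinc genes, 12 were higher and 1 lower in mRNA (median 1.42; the zinc-regulated ZPS1 7.83 ± 0.14, the zinc-regulated alcohol dehydrogenase ADH4 4.65 ± 0.10, the zinc transporter ZRT1 4.30 ± 0.11). Of 41 respiratory genes, 39 were higher and 1 lower in mRNA (median 1.71; QCR10 2.57 ± 0.16, NDE1 2.41 ± 0.14), and 40 were higher in footprints (median 1.20). Mitochondrial open reading frames took 11.7% of the CMP mRNA reads. Of 26 ergosterol genes, 24 were lower and 1 higher in mRNA (median -1.03; ERG6 -2.31 ± 0.13, the sterol regulator UPC2 -2.05 ± 0.18), and 22 were lower in footprints (median -1.34). The phosphate transporter PHO84 was higher in CMP (4.12 ± 0.23). The sorbitol dehydrogenase genes stood far above the others, SOR1 at 1540 ± 440 CPM (SD, n = 2) against 30.7 and SOR2 at 1500 against 29.7, though reads of these near-identical copies could have been split. HXT13 was higher by 8.07 ± 0.13. The mRNA counts of the 4 lists were the same adjusted over the list alone. By camera with Benjamini-Hochberg adjustment, adjusted p was 2.8e-11 for thiamine, 1.7e-06 for copper and zinc, 1.1e-18 for respiration and 6.3e-12 for ergosterol in mRNA, and adjusted p = 0.1, 0.35, 0.42 and 0.32 with an estimated correlation. For footprints, the thiamine call stood with an estimated correlation (adjusted p = 0.023), as did the respiratory call (0.04).

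In CPI the biotin, storage carbohydrate and cell wall genes were higher and the iron regulon lower. All 6 biotin genes rose in mRNA (median 2.15; the biotin ligase BPL1 2.44 ± 0.10, BIO5 2.38 ± 0.11, BIO3 2.35 ± 0.12) and in footprints (median 2.32). Of 28 iron regulon genes, 19 fell and 9 were not called in mRNA (median -1.20; the siderophore transporter ARN1 -3.96 ± 0.19, the ferric reductase FRE4 -2.98 ± 0.40). In footprints 20 fell (median -1.33), with the largest changes in the cell wall mannoproteins FIT2 (-5.57 ± 0.33) and FIT3 (-5.17 ± 0.33) and in ARN1 (-5.10 ± 0.23). Of 16 trehalose and glycogen genes, 14 rose and 2 were not called in mRNA and again in footprints (median 1.22 in each; TSL1 2.12 ± 0.18 and GPH1 1.88 ± 0.16 in mRNA). Of 29 cell wall genes, 25 rose and 1 fell in mRNA (median 1.25; TIP1 3.74 ± 0.093, TIR1 3.14 ± 0.20), and 21 rose and 1 fell in footprints. SCEI, the mitochondrial intron endonuclease gene, was at 1010 ± 42 CPM in mRNA (SD, n = 2) against 64.2 in the others and had 0 footprint reads. The 0 does not show a lack of translation, since the others had 0.755 CPM of SCEI footprints, below the CPI floor of 1.05 CPM. Mitochondrial open reading frames took at most 0.0268% of the footprint reads of any library. PAU21, with near-identical copies, was counted lower (-5.15 ± 0.80). The mRNA counts of the 4 lists were the same adjusted over the list alone, and 21 iron genes fell in footprints on that basis. Adjusted p by camera with Benjamini-Hochberg adjustment was 5.1e-05 for biotin, 6.9e-09 for iron, 0.00024 for trehalose and glycogen and 1.7e-07 for the cell wall in mRNA, and adjusted p = 0.35, 0.35, 0.56 and 0.29 with an estimated correlation. For iron footprints camera gave adjusted p = 3.1e-13, and adjusted p = 0.04 with an estimated correlation.

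In CQC glycolysis and the ribosomal proteins were lower, and stress, fatty acid oxidation and nitrogen-scavenging genes were higher. Of 25 glycolysis genes, 22 fell and 1 rose in mRNA (median -3.30; ENO2 -8.34 ± 0.27, TDH2 -6.96 ± 0.18, ENO1 -6.23 ± 0.24), and 21 fell and 1 rose in footprints (median -3.03; ENO2 -4.21 ± 0.25, GPM1 -4.19 ± 0.23). Of 137 ribosomal protein genes, 135 fell in mRNA (median -1.67; RPS15 -2.71 ± 0.24, RPL13B -2.64 ± 0.14) and 135 fell in footprints (median -1.69). Of 32 general stress genes, 23 rose and 4 fell in mRNA (median 1.66; GRE1 6.07 ± 0.13, the Hsp70 SSA3 5.28 ± 0.13, SIP18 5.14 ± 0.15), and 28 rose and 3 fell in footprints (median 2.25). Of 17 peroxisomal and fatty acid oxidation genes, 15 rose and 1 fell in mRNA (median 2.13; the thiolase POT1 4.26 ± 0.17, SPS19 3.96 ± 0.17, the catalase CTA1 3.81 ± 0.13). Of 22 nitrogen catabolite repressed genes, 20 rose and 1 fell in mRNA (median 1.62; the proline permease PUT4 4.65 ± 0.15, PUT1 4.61 ± 0.15, the general amino acid permease GAP1 4.10 ± 0.15). All 10 daughter-specific genes fell in mRNA (median -2.36; the glucanase DSE4 -4.71 ± 0.28, EGT2 -3.89 ± 0.32). Of 41 respiratory genes, 30 were higher and 4 lower in mRNA (median 1.15), and 39 were higher in footprints (median 1.97). TE rose for 27 of them and was not called for 14 (median 0.75; 35 higher adjusted over the list alone). Camera with Benjamini-Hochberg adjustment gave adjusted p = 4.5e-16 for this TE list, which was lost with an estimated correlation (adjusted p = 0.94). With the trend with coding length removed, TE rose for 13 of these genes (median 0.54). Mitochondrial open reading frames took 20.2% ± 1.5 of the CQC mRNA reads (SD, n = 2), the highest share of the 8 isolates. The spore wall gene SPS100 (7.72 ± 0.24) and HXT5 (7.0 ± 0.13), a hexose transporter of slow growth, were the other genes named by rule. Adjusted over the list alone, only the respiratory counts moved in mRNA, to 31 higher and 5 lower. By camera with Benjamini-Hochberg adjustment, adjusted p was 1.4e-09, 2.5e-28, 0.00011, 2.7e-06, 4.5e-06, 0.0025 and 5e-05 for the mRNA of the 7 lists in the order given, and adjusted p = 0.35, 0.46, 0.6, 0.35, 0.17, 0.52 and 0.62 with an estimated correlation.

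**Figure D2:**
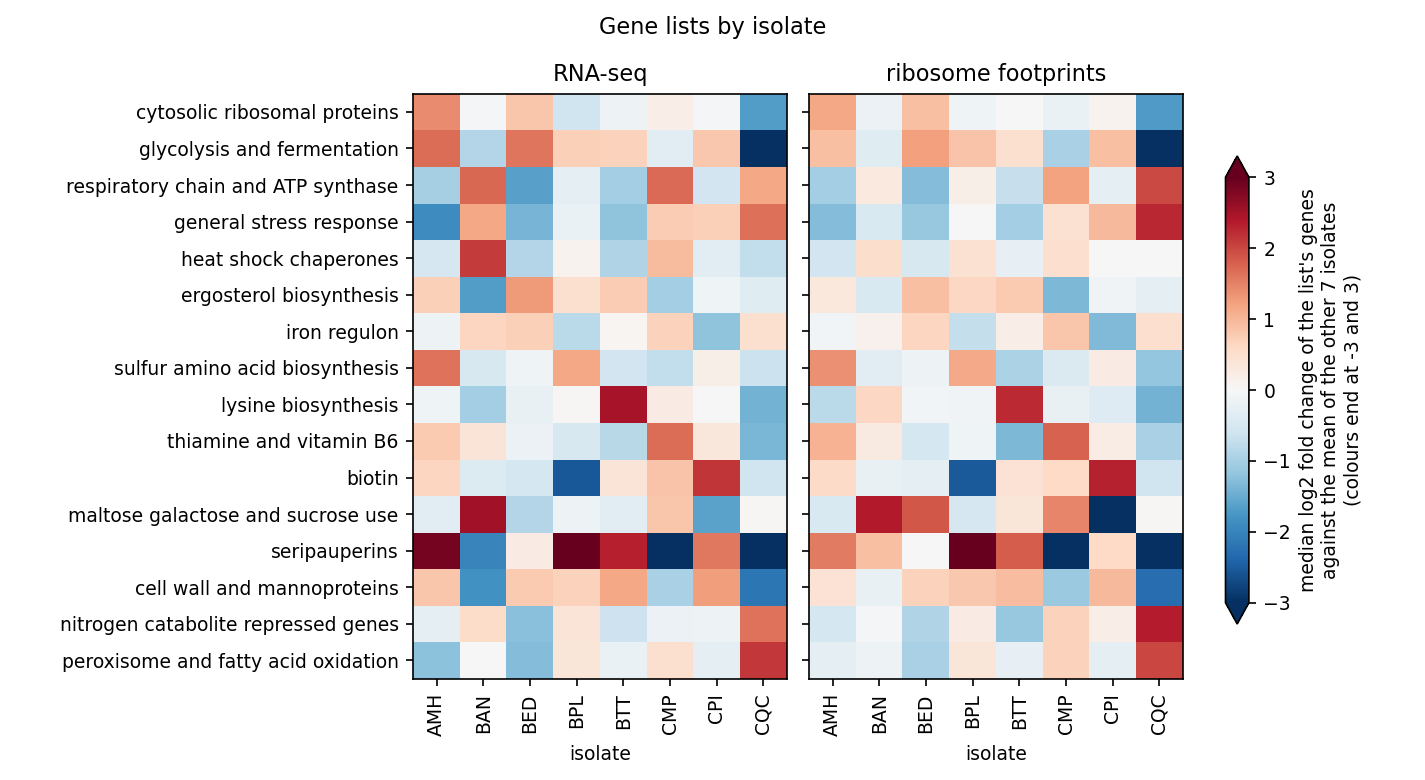
Median log2 fold change of 16 gene lists (vertical axis) in each isolate against the mean of the other 7 (horizontal axis), for mRNA and for footprints, on a colour scale that ends at -3 and 3. The CQC glycolysis list has the lowest of the values quoted for mRNA (-3.30), and the BAN heat shock list is at 2.09 in mRNA and 0.52 in footprints.

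Counted over all genes, the mRNA calls per isolate were 2094 higher and 1904 lower in AMH, 2130 and 2077 in BAN, 2059 and 1846 in BED, and 1736 and 1196 in BPL. They were 2061 and 1248 in BTT, 1731 and 1645 in CMP, 1970 and 1407 in CPI, and 2231 and 2328 in CQC. Without the second BPL mRNA library the BPL count went from 2932 to 1596, and without the first BTT mRNA library the BTT count went from 3309 to 2068. Camera called 244 of 448 combinations of list and isolate in mRNA, 227 in footprints and 114 in TE, and with an estimated correlation 6, 5 and 0 of them stood. The mRNA calls that stood included the vesicle coat and exocyst genes, COPI and COPII, in BAN, where 22 of 23 fell (23 adjusted over the list alone; median -1.14; adjusted p = 0.035 with an estimated correlation, RET2, COP1 and SEC27 changing most). In BAN footprints 0 of the 23 were called (median -0.26; 0 adjusted over the list alone), and TE rose for 11 and fell for 0 (12 and 0 adjusted over the list alone; median 1.12). By camera with Benjamini-Hochberg adjustment this gave adjusted p = 0.37 and 9.8e-05, and adjusted p = 0.57 and 0.74 with an estimated correlation. Medians relate to the middle gene of each comparison, since another scaling of the libraries moved the median of all genes by 0.108 in BAN mRNA, 0.114 in CQC footprints and 0.101 in CQC TE. No list median beyond 0.2 in size changed sign with it.

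Footprints differed among the isolates for 3909 of 5347 genes (73.1%), with a median of 1428 genes for a pair of isolates, from 110 between BAN and CMP to 2933 between BTT and CQC. In CQC, the stress gene GRE1 rose by 6.69 ± 0.16 in footprints against 6.07 ± 0.13 in mRNA, ENA1 by 5.83 ± 0.19 against 6.03 ± 0.14, and GAP1 by 4.21 ± 0.34 against 4.10 ± 0.15. PHO84 was higher in mRNA in CMP (4.12), BAN (3.19) and AMH (2.06) and lower in CPI (-3.41), BED (-3.28) and BPL (-2.14). HO, the mating-type switching endonuclease, passed the read filter only in mRNA, where it was higher in BAN (2.98) and lower in BED (-1.88). Its mean was 7.92 ± 7.8 CPM in BAN (SD, n = 2), so the BAN libraries differed widely, and 0.489 ± 0.026 CPM in BED. CUP1-1, the copper metallothionein gene, had 0 mRNA reads and was not tested. Per isolate, the footprint calls were 1063 higher and 750 lower in AMH, 174 and 52 in BAN, 1115 and 741 in BED, and 861 and 484 in BPL. They were 1001 and 704 in BTT, 608 and 392 in CMP, 949 and 642 in CPI, and 1401 and 1246 in CQC. Of the genes called in mRNA and in footprints, the share with the same sign was 97.9% in AMH, 98.2% in BED, 95.2% in BPL, 95.1% in BTT, 91.8% in CMP, 96.9% in CPI, 97.9% in CQC and 78.2% in BAN. The footprint count dropped by over 1.5 times without 1 library in AMH (876 without its second), BAN (125 without its first, 111 without its second), BED (1134 without its second), BPL (876 and 653), CMP (557 and 581) and CPI (949 and 1059). With DESeq2 the BAN count was 347, and in BED it was 1156 when BAN, CMP and CQC, the isolates with the shallowest footprint libraries, were left out.

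TE differed among the isolates for 1643 of 5337 genes (30.8%), with a median of 420 genes for a pair of isolates, from 61 between BPL and BTT to 791 between BAN and BTT. In AMH the acid phosphatase genes PHO12 (TE 5.21 ± 0.31, edgeR with Benjamini-Hochberg adjusted p = 5.8e-12) and PHO11 (4.90 ± 0.24), near-identical copies that could share reads, were lower in mRNA (-2.58 and -2.19) and higher in footprints (2.71 and 2.78). AIM29 had a TE of 4.64 ± 0.45 above the others. In BPL the low-affinity glucose transporter HXT1 was higher in mRNA by 5.04 ± 0.19 and not called in footprints (0.45 ± 0.17), so that its TE fell (-4.60 ± 0.33, adjusted p = 2.93e-10). The spindle checkpoint kinase gene BUB1 was not called in BPL mRNA (0.03 ± 0.20) and fell in footprints (-3.53 ± 0.54; TE -3.58 ± 0.66), and COS6, of a near-identical family, had a higher TE (3.33 ± 0.24). In CMP the pyruvate decarboxylase PDC5 rose by 4.36 ± 0.11 in mRNA and 0.72 ± 0.16 in footprints (TE -3.58 ± 0.23, adjusted p = 6.81e-11), and SPS100 had a higher TE (4.95 ± 1.1). SPS100 was at 0.672 CPM in CMP mRNA and 69.8 CPM in CMP footprints. The means of the others, 85 and 481 CPM, take in CQC at 537 and 3190 CPM. On the log2 scale SPS100 fell in CMP mRNA (-3.29 ± 0.77) and rose in CMP footprints (1.58 ± 0.53). In BED the respiratory regulator ZNF1 (4.79 ± 0.74), the reductase FRE7 (4.55 ± 0.81) and IMA3 (4.48 ± 0.39) had a higher TE. Their BED mRNA was at 0.884, 0.44 and 5.45 CPM. Their BED footprints were at 10, 31.4 and 136 CPM, against means of 72.2, 219 and 329 CPM in the others. On the log2 scale BED footprints fell for ZNF1 (-2.09 ± 0.37) and FRE7 (-1.79 ± 0.32). For IMA3 they rose (1.88 ± 0.23) while its mRNA fell (-2.63 ± 0.27). The IMA3 mean of the others takes in BAN, at 1610 CPM of footprints. The sources of footprints weighed below for FIT2, FIT3 and ARN2 in BED were not tested for these genes. In BTT HXT5 (3.24 ± 0.31) and FCY22 (3.14 ± 0.32) had a higher and VTH1 (-2.60 ± 0.25) a lower TE. In CPI the maltases MAL12 (-4.38 ± 0.51) and MAL32 (-3.64 ± 0.41) had a lower TE and FLO1 (2.37 ± 0.47) a higher TE. In CQC PAU19 had a lower TE (-6.56 ± 0.97) and ENO2 a higher TE (4.14 ± 0.28). ENO2 stood at 8.71 CPM in CQC mRNA and 930 CPM in CQC footprints, against 4630 and 18500 CPM in the others. It thus fell in both assays, and the source of its remaining footprints was not tested. HXT, MAL, FLO, PAU and IMA genes and VTH1 could share reads with copies. GCN4, the amino acid starvation regulator held back by upstream reading frames, had a mean log2 TE of -3.91 ± 0.66 (SD over the 8 isolates) and a higher TE in CQC (1.28 ± 0.31, adjusted p = 0.00728).

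Genes with 0 footprint reads in both libraries of an isolate give bounds. In CQC the condensin gene YCG1 was at least 4.77-fold lower in footprints (27.3 CPM in the other 7 isolates, against a floor of 3 reads over both libraries, 5.72 CPM), beside 37.5 against 92.6 CPM in mRNA. DSE3 was at least 4.67-fold lower in CQC footprints, beside 11.6 against 45.1 CPM in mRNA. In BAN, where the floor was 33 CPM, the bounds were 2.85-fold for the helicase gene DBP1, 1.72-fold for the sorting factor HSE1 and 1.31-fold for GPC1. The footprint difference itself was called for HSE1 but not for DBP1 or GPC1 (edgeR with Benjamini-Hochberg adjusted p = 0.0463, 0.211 and 0.155). LNP1 was at least 1.85-fold lower in CMP footprints. Each of these 6 TE calls was lost when a footprint library of its own isolate was left out. By edgeR's adjusted p, YCG1 stood at 0.105 and DSE3 at 0.241 without the second CQC footprint library, DBP1 at 0.448, HSE1 at 0.218 and GPC1 at 0.352 without the first BAN library, and LNP1 at 0.267 without the first CMP library. Among the TE genes with reads, adjusted p rose to 0.225 for SPS100 in CMP, 0.093 for BUB1 in BPL and 0.053 for FRE7 in BED without 1 footprint library, the first of CMP, the second of BPL and the second of BED, by edgeR with Benjamini-Hochberg adjustment. For FLO1 in CPI it rose to 0.0645 without the isolates BAN, CMP and CQC.

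Over all genes, TE was higher for 166 and lower for 454 genes in AMH, 351 and 395 in BAN, 118 and 174 in BED, and 97 and 180 in BPL. The counts were 94 and 225 in BTT, 212 and 73 in CMP, 69 and 181 in CPI, and 473 and 128 in CQC. In CMP the share of higher calls was 74.4%, and 63.9% when the libraries were scaled by the DESeq2 method. Of the genes called in TE, 64 in CMP, 68 in BTT, 41 in BAN, 33 in AMH, 28 in BED, 47 in BPL, 40 in CPI and 49 in CQC were called in opposite directions in mRNA and in footprints, 247 distinct genes. RIC1, which takes part in Golgi recycling, was so called in 7 isolates, and the glucosyltransferase gene ALG6 in 6, though the contrasts share libraries. TE counts moved with single libraries. Leaving out the first footprint library of AMH gave 303 calls there, and leaving out the first of BAN gave 383 in AMH, 217 in BAN and 206 in BTT. In BED the count was 159 and 134 without each mRNA library and 91 and 97 without each footprint library of its own, in BPL 158, 151, 100 and 81 likewise, and in CPI 148, 135, 101 and 135. In BTT it was 206 and 186 without each mRNA library and 143 without the second footprint library, in CMP 89 without the second footprint library, and in CQC 293 without the first mRNA library and 246 and 323 without each footprint library. Without the first BAN mRNA library it was 509 in BPL, 554 in BTT and 440 in CPI, and without the second 448 in CMP. Without BAN, CMP and CQC the counts were 1089 in AMH, 188 in BED and 187 in BTT, and with DESeq2 443 in BPL, 491 in BTT, 494 in CMP and 389 in CPI.

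Where mRNA and TE both differed among isolates, TE moved against mRNA for most genes. HXT13 had an SD among isolates of 4.72 on the log2 scale in mRNA and 3.70 in footprints, with a slope of footprints on mRNA of 0.779 (TE omnibus adjusted p = 8.59e-05 by edgeR with Benjamini-Hochberg adjustment), and HXT17 had a slope of 0.805. Both have near-identical copies, as do SOR1 (0.73) and SOR2 (0.743). The siderophore transporter ARN2 (0.367), FIT2 (0.616), FIT3 (0.561) and the ferric reductase FRE5 (0.392) completed the 8 most variable genes classed so. Their mRNA had 0 or 1 reads in BED, and in BPL or CQC, so that these slopes hang on the prior count. Over the 6 isolates with more than 3 mRNA reads, the slope was 1.0 for ARN2 and 1.09 for FIT3, which no longer moved against mRNA. It was 0.816 for FIT2, 0.64 for FRE5, 0.80 for SOR1 and 0.838 for SOR2. ZPS1 (SD 3.29 in mRNA and 3.64 in footprints, slope 1.09) led the most variable genes with the opposite pattern. The others were SNZ1 of vitamin B6 synthesis (1.05), VID24 of gluconeogenic enzyme degradation (1.02), IMA1 (1.32), and the copied genes PAU20 (1.14), PAU11 (1.03), FLO9 (1.04) and FLO5 (1.03). Each gene was classed by the sign of a covariance that had no test of its own. Slopes as near 1 as that of VID24 therefore show no clear direction. Of 1631 genes called in mRNA and in TE, TE moved against mRNA for 1476 (90.5%) and with it for 155. Of the other genes tested, the covariance of TE and mRNA differences was negative for 73.7%. Of 5232 genes called in mRNA among the 5337 tested for TE, 3601 (68.8%) were not called in TE, which does not show that their footprints followed mRNA in full. Without BAN, CMP and CQC the first count was 932, and without the first BAN mRNA library the second was 236.

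The slope of footprint on mRNA differences over 5337 genes was 0.597 ± 0.10 (jackknife SE over 8 isolates), and 0.718 ± 0.11 over the 1362 genes with at least 100 reads. The value over 5337 genes depends on counts and on the prior: a slope simulated at 1 came out at 0.928, and the observed slope was 0.651 with mRNA thinned to the footprint totals and 0.691 with a common prior of 2 CPM. The slope of mRNA on footprint differences was 0.969 ± 0.059 and 1.01 ± 0.071. The variance among isolates in footprints was 0.616 times that in mRNA (SE 0.12). An exact two-sided permutation test that swapped the assays within isolates gave p = 0.0078, the smallest p it can give. The ratio was 0.708 (SE 0.14, exact p = 0.016) over the 1362 genes. With the same prior of 2 CPM in both assays the ratio was 0.788 (exact p = 0.07), and over the 5 isolates with the deeper footprint libraries it was 0.517 (exact permutation p = 0.062, the smallest possible with 5). Over the 1362 genes the slope was 0.70 in AMH, 0.286 in BAN, 0.695 in BED, 0.784 in BPL, 0.752 in BTT, 0.737 in CMP, 0.728 in CPI and 0.948 in CQC. Among 28 pairs of isolates it was below 1 in 28, with a median of 0.75 and a range of 0.365 to 0.922. The variance ratio of the same pairs was below 1 in 25 of 28 (median 0.738), and it was 1.55 between BAN and CMP and 1.3 between BAN and CQC. For CQC against the mean of the isolates the ratio was 1.04. In BAN, 192 of these genes were up in mRNA by a median of 1.66 and stood at 0.51 in footprints, and 204 were down by a median of -1.46 and stood at -0.13.

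**Figure D3:**
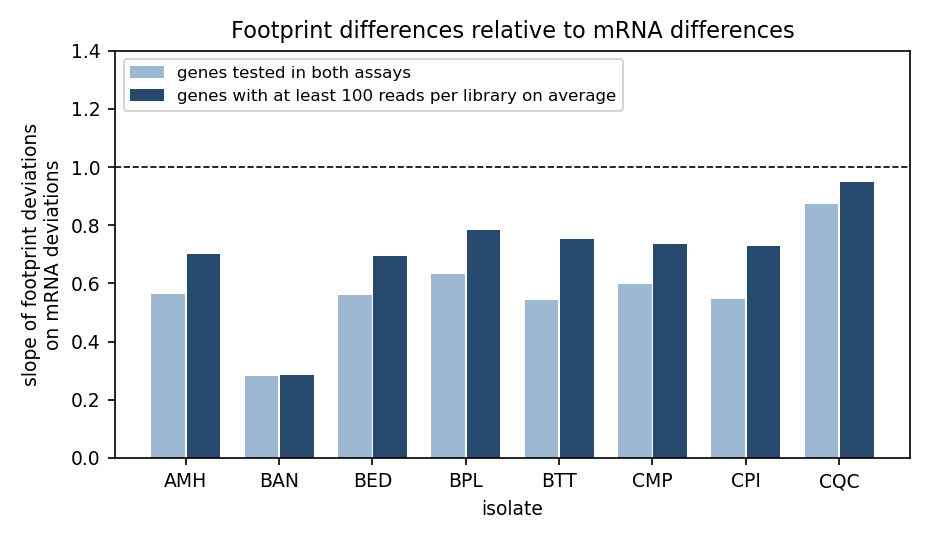
Slope of footprint on mRNA differences for each isolate (horizontal axis), as paired bars from 0. The pairs cover all genes and the 1362 genes with a mean of at least 100 reads. A dashed line at 1 marks where footprints would follow mRNA in full. All bars lie below 1, from 0.286 in BAN to 0.948 in CQC over the 1362 genes.

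By gene group, ribosomal protein genes (slope 0.819) and thiamine and vitamin B6 genes (0.956) had higher slopes than random lists matched on mRNA level, and the nuclear pore (0.44) and the translation initiation factors (0.481) had lower ones. The adjusted permutation p over 54 lists was 0.022, 0.035, 0.035 and 0.035 in that order. Matched also on the variance among isolates, 1 list lay below (the spliceosome, 0.291, adjusted p = 0.023 by permutation) and 5 above, and without BAN none lay below or above (0 and 0). In 5 bins of mRNA level the slope was 0.493, 0.569, 0.668, 0.694 and 0.729 from the lowest to the highest. With the mRNA libraries thinned to the footprint totals the bins stood at 0.646, 0.612, 0.643, 0.642 and 0.711, so that the rise was smaller with the library totals matched.

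Baseline TE was taken over 1310 genes with a symbol and a mean of at least 100 reads per library in both assays. It was highest for TIR1, a cell wall mannoprotein (mean log2 TE 7.22, SD 1.5 over the 8 isolates), and HXT1 (6.33, SD 1.8). PAU21 and PAU22 (SD 2.7 each), copies that could share reads, and FIT3 (5.48, SD 2.4) followed. The FIT3 mean takes in BED and BPL, with 0 and 1 mRNA reads, and is not exact. It was lowest for the lipid transfer protein gene VPS13 (-2.25, SD 0.61) and the ubiquitin ligase gene TOM1 (-2.16, SD 0.29), followed by the glutamate synthase GLT1 (-1.94), NAB6 (-1.94) and RRP5 (-1.91). The median was 0.11.

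Some genes had at most 3 mRNA reads over both libraries of an isolate and at least 10 CPM elsewhere. There were 3 such genes in AMH, 14 in BAN, 29 in BED, 21 in BPL, 1 in BTT, 27 in CMP, 5 in CPI and 10 in CQC. Of these, 2, 0, 11, 9, 0, 8, 3 and 2 had a symbol, in the same order. How reads of repeated sequences were counted is not known, so these are not counts of missing genes. In BED and BPL these included a stretch on chromosome XV (sacCer3) that holds FIT2 (YOR382W, 1059531 to 1059992), FIT3 (YOR383C, 1060441 to 1061055) and FRE5 (YOR384W, 1061564 to 1063648). FIT2 had 1 mRNA read in BED and 0 in BPL, FIT3 0 and 1, and FRE5 0 and 0, against 136, 75.1 and 96.1 CPM elsewhere. PHR1, the photolyase gene (YOR386W, 1066839 to 1068536), had 0 mRNA reads in BPL, against 84.8 CPM elsewhere, and 0 of 53.4 expected footprint reads, which allows up to 6.91%. ARN2 (YHL047C, chromosome VIII, 8351 to 10213) had 1 mRNA read in BED and 1 in CQC, against 451 CPM elsewhere. In BED these genes had footprint reads, 669 on FIT3, 356 on FIT2, 48 on ARN2 and 10 on FRE5. For the first 3 they came to 17.6% (exact 95% interval 16.3 to 19.0), 9.81% (8.81 to 10.9) and 11.6% (8.55 to 15.4) of the reads their level elsewhere would give. The BED libraries differed by more than these intervals on FIT3 (593 and 202 CPM) and FIT2 (308 and 112 CPM), while ARN2 had 34.2 and 20.2 CPM. In BPL FIT2 had 36 footprint reads, 1.09% (0.762 to 1.51) of that level, and in CQC ARN2 had 6, 5.04% (1.85 to 11). IRC7, a cysteine lyase gene, had 0 mRNA reads and 1 footprint read in AMH. HXT8 had 0 mRNA reads and 233 footprint reads in CPI, where copies could share reads. RFA3 had 3 mRNA reads in CQC, and 8 subtelomeric YRF1 copies had 0 in CMP. Footprint reads on these copies in CMP ran from 1 on YRF1-8, where their level elsewhere would give 1.86, to 11 on YRF1-2, where it would give 2.46. Such copies could share reads. The intervals cover counting error only.

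**Figure D4:**
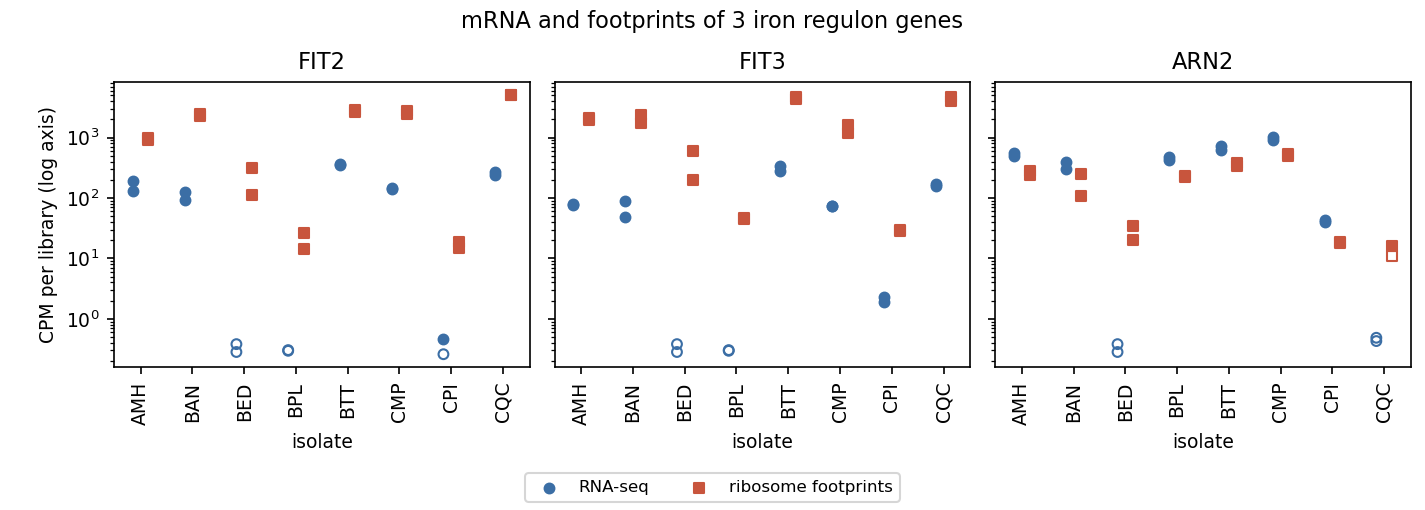
CPM of FIT2, FIT3 and ARN2 (log axis) in each of the 32 libraries, by isolate, for mRNA and for footprints; open symbols are libraries below the floor of 3 reads, drawn at the floor. FIT2 and FIT3 in BED are at the floor in mRNA and well above it in footprints.

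Shifts of whole nuclear chromosomes depended on the genes used. Of 128 combinations of isolate and chromosome, 0 had a median mRNA difference beyond 0.3 on the log2 scale in both replicates, and the largest mean of both replicates was 0.228, for chromosome X in BED. A single replicate passed for chromosome I in BAN (-0.333, against -0.0132 in the other). Restricted to the 1362 genes with at least 100 reads, 7 combinations passed that limit. In BED they were chromosomes I (0.431 and 0.611), IX (0.38 and 0.388), X (0.349 and 0.311) and XIII (0.313 and 0.311). In CQC they were chromosomes I (-0.633 and -0.628), III (-0.611 and -0.511) and IX (-0.571 and -0.477). Over all genes the median of CQC chromosome IX was positive (0.18 and 0.129).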

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

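The tests on mRNA-wide damping, on mixing, coding length and depth beyond the slope in BAN, and on iron gene members, other isolates and related genes in BED were chosen after the result was seen; the other tests were set before it.

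The BAN isolate stood apart from the other 7 in 4 of 13 measures by Dixon's criterion, which chance exceeds in about 1 of 20 groups. They were the slope of footprint on mRNA differences (0.286) and the correlation of these differences (0.547). The share of genes called in both assays with the same sign (78.2%) and the correlation of its footprint replicates (0.797) were the others. The slope and both correlations were over genes with a mean of at least 100 reads across all libraries of an assay. The BAN footprint libraries themselves held 63336 and 27621 reads in all. BAN also had 41 genes called in opposite directions in mRNA and footprints with the TE difference itself called, within the 28 to 68 of the isolates. With each other isolate thinned to the BAN totals, the lowest slope was 0.75, the lowest correlation of differences 0.816 and the lowest same-sign share 93%, which argues against depth for these, but the lowest replicate correlation was 0.784, so depth can account for that of BAN; with the trends with coding length removed the BAN slope was 0.292, which argues against length. Footprints of other isolates in the BAN libraries stay open as an explanation of the slope, since the counts allow a share of up to 0.777. This upper limit takes in counting error and so widens in shallow libraries, and it does not show that such footprints are present. The next largest limit, 0.187, was that of CMP, whose footprint libraries were the next shallowest. A stronger damping of mRNA differences in this isolate stays open too, as does variation held by the BAN mRNA libraries alone, which was not tested. These explanations cannot be told apart here. Both BAN footprint libraries gave low slopes, 0.186 and 0.387, against 0.623 to 0.97 in the libraries of the others, so a single failed library may be set aside.

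In BED, footprint reads lay on genes without mRNA reads: 669 on FIT3, 356 on FIT2 and 48 on ARN2, where the mRNA libraries held 0, 1 and 1 reads. Short footprints of related genes are argued against for FIT3 and FIT2, since BPL, which also lacked their mRNA, had 0.126 times (0.0983 to 0.16) and 0.112 times (0.0775 to 0.159) the BED level, and stay open for ARN2, where CQC, which lacked its mRNA, had 0.44 times (0.154 to 1.03). Footprints of BTT, the isolate with the deepest libraries, as the source for the whole set of 10 genes are also argued against. Of 20 values, 2 lay below 0.5 times the pooled share, FIT3 and FIT2 in the second library. YOR314W, at 239% and 260% of its BTT level, held more than BTT footprints could give. This argues against BTT for the set, not for FIT3 and FIT2 themselves. For the iron regulon members alone, equal shares of the BTT level were not excluded (multinomial permutation p = 0.14 and 0.42, with pooled shares of 12.4% and 4.44%). So a transfer of BTT footprints could account for these genes, as could one from AMH in part, which reaches at most 236 of the 397 CPM of FIT3. No biological explanation, such as diverged copies that only footprint reads match, was tested.

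Over all isolates, footprint differences followed mRNA differences with a slope of 0.718 over genes with at least 100 reads. Depth as the whole cause is neither shown nor excluded. With mRNA thinned to the footprint totals the slope was 0.714, more than 2 SE below 1 (upper limit 0.991). A slope simulated at 1 at the real depths came out at 0.965, which lies within 2 SE of the thinned slope, so this test cannot decide. An even damping of every gene as the only difference between the assays is argued against. Alone it would put the slope of mRNA on footprint differences at 1.39, and 1.01 (SE 0.071) was observed. Even damping together with differences held by footprints alone was not tested and stays open, because such differences also lower that slope. The value could also come from mRNA differences of which a part is absent from footprints, with the footprint differences present in full in mRNA. A candidate explanation is translation that offsets part of the mRNA differences, and another is variation that entered the mRNA libraries alone; the isolates' 2 libraries per assay cannot separate them.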

How the results depend on the processing

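The alternatives with 5 isolates, thinned mRNA, a common prior of 2 CPM or 2 choices together, and the list slopes without BAN, were chosen after seeing the data. Of 847 other values of 40 results, 772 stayed on the same side of the threshold or within 1.5 times, and 75 did not; of 1374 values of named genes, 1339 were unaltered, 35 lost their call (10 genes) and 0 reversed. The BAN, CMP and CQC footprint libraries were the shallowest; in simulated counts for BAN, 8.6% of genes changed by 1 on the log2 scale were called in footprints, against 57.1% for BPL. With DESeq2, calls were 347 in BAN footprints and, in TE, 443 in BPL, 491 in BTT, 494 in CMP and 389 in CPI. Over 5 isolates (without BAN, CMP and CQC) they were 1156 in BED footprints and 1089 in AMH, 188 in BED and 187 in BTT TE, with 932 genes of TE against mRNA; fewer libraries entered. The slope was 0.718 over genes with at least 100 reads, 0.751 with 5 isolates as well and 0.714 with mRNA thinned as well. The variance ratio was 0.788 with a common prior of 2 CPM (exact permutation p = 0.07), and 0.517 and, over genes with at least 100 reads, 0.724 with 5 isolates (exact p = 0.062, the smallest possible). Lists below and above random were 1 and 5 matched on variance, 0 and 0 without BAN, and 0 and 0 over 5 isolates. The slope of the lowest mRNA bin was 0.413 with a prior of 10, 0.678 over genes with at least 100 reads and 0.646 with mRNA thinned, and 7 chromosome shifts passed over genes with at least 100 reads. Except where fewer libraries or genes entered, the cause was not tested.

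Within an isolate, mRNA and footprint deviations of the same number correlated positively in all 8 isolates, from 0.0822 in BAN and 0.111 in CQC to 0.72 in CPI, so each sample correlated best with its own number. This is a hint from the data that same-numbered libraries belong together, not a part of the design. The labels do not say so, and BAN fell short of the limit of 0.1 set for every pair, so the samples were not treated as paired. Across isolates the medians were 0.0401 in mRNA and 0.0209 in footprints. With a replicate block, TE calls were 2468 over all isolates, 1022 in AMH, 603 in BED, 714 in BPL, 903 in BTT, 496 in CMP, 653 in CPI and 909 in CQC, and 314 genes had TE moving with mRNA; the slope was 0.615. The cause was not tested.

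Leaving out each library in turn, with the lone remaining library assumed to vary like those of other groups, gave these ranges. In mRNA, 5980 to 6243 genes differed among isolates, and calls ran from 3279 to 4321 in AMH, 3815 to 4468 in BAN, 2902 to 4251 in BED, and 1596 to 3531 in BPL. They ran from 2068 to 3759 in BTT, 2370 to 3834 in CMP, 2339 to 3806 in CPI and 3907 to 4777 in CQC, where the second BPL and the first BTT library gave the lowest values of their isolates. In footprints, 3653 to 3953 genes differed, and calls ran from 876 (second AMH library) to 1887 in AMH, 111 (second BAN library; 125 without the first) to 266 in BAN, 1134 (second BED library) to 1906 in BED, and 653 (second BPL library; 876 without the first) to 1407 in BPL. They ran from 1197 to 1761 in BTT, 557 (first CMP library; 581 without the second) to 1075 in CMP, 949 (first CPI library; 1059 without the second) to 1693 in CPI and 2086 to 2685 in CQC.

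In TE, 1406 to 2048 genes differed, and calls ran from 303 to 693 in AMH, 217 to 1027 in BAN, 91 to 393 in BED, and 81 to 509 in BPL. They ran from 143 to 554 in BTT, 89 to 448 in CMP, 101 to 440 in CPI and 246 to 821 in CQC. TE counts moved by over 1.5 times without the first AMH footprint library (303 in AMH) and the first BAN footprint library (383 in AMH, 217 in BAN, 206 in BTT). They also moved without either mRNA or footprint library of its own in BED (159 and 134, then 91 and 97), BPL (158 and 151, then 100 and 81) and CPI (148 and 135, then 101 and 135). Without a library of its own, BTT gave 206 and 186 (mRNA) and 143 (second footprint library), CMP 89 (second footprint library), and CQC 293 (first mRNA library) and 246 and 323 (footprints). The first BAN mRNA library moved BPL to 509, BTT to 554 and CPI to 440, and the second moved CMP to 448. Genes with TE against mRNA ran from 1227 to 1807, and those with it from 115 to 236, the latter without the first BAN mRNA library. The cause was not tested.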

Other observations

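The genes called in opposite directions in 5 or more isolates and the length correlations were singled out after their values were seen, as was the length correction of the lists; the other list tests here were set before.

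In CQC further gene groups changed. Of 20 cytosolic tRNA synthetase genes, 18 fell in CQC mRNA (18 adjusted over the list alone) and 20 in footprints (median -1.56 and -1.74). The largest mRNA changes were in the glutamyl enzyme GUS1 (-2.87 ± 0.12, SE, 2 libraries against 14) and the tyrosyl enzyme TYS1 (-2.20 ± 0.13). Of 35 genes of the G1 to S transition and DNA replication, 30 fell and 1 rose in mRNA (31 and 1 adjusted over the list alone; median -1.63), among them the ribonucleotide reductase RNR1 (-4.21 ± 0.18) and the cyclin CLN1 (-4.20 ± 0.27). Of 23 genes of mitosis and cytokinesis 18 fell and 4 rose (median -2.10), led by the cyclin CLB2 (-3.47 ± 0.22) and the transcription factor SWI5 (-3.45 ± 0.35). All 17 vacuolar ATPase genes fell in mRNA (median -1.10; VMA5 -3.0 ± 0.15), as did 15 of 17 purine synthesis genes (median -1.25; ADE3 -3.37 ± 0.12). In CQC 16 of 24 genes of the TCA and glyoxylate cycle rose while 5 fell (median 1.21; malate synthase MLS1 5.0 ± 0.11, acetyl-CoA synthetase ACS1 4.47 ± 0.17), beside a mitochondrial share of 20.2% of mRNA reads. Of 23 coat and exocyst genes, 21 fell and 1 rose (median -1.16; SEC27 -2.58 ± 0.14), and 22 fell in BAN (median -1.14). The camera test with Benjamini-Hochberg adjustment gave adjusted p = 1.3e-07, 5.2e-06, 0.0034, 1.6e-05, 6.1e-05, 0.0025 and 5.1e-07 for the mRNA of these lists in the order given, and adjusted p = 0.29, 0.45, 0.52, 0.46, 0.35, 0.55 and 0.035 with an estimated correlation.

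In BED, genes of the TCA and glyoxylate cycle, fatty acid oxidation and stress were lower beside its low respiratory genes. There 17 of 24 TCA and glyoxylate genes fell and 1 rose in mRNA (median -1.38; PCK1 -4.44 ± 0.24, FBP1 -4.03 ± 0.30), and 14 of 17 peroxisomal genes fell (median -1.30; CRC1 -3.79 ± 0.21). In addition 25 of 32 stress genes fell and 2 rose (median -1.39; HSP30 -6.26 ± 0.47). Protein folding genes of the endoplasmic reticulum were higher in BED, with 15 of 19 up and 1 down (median 1.08; MPD1 1.85 ± 0.15, EUG1 1.63 ± 0.12). In BAN, replication genes were lower in mRNA, with 31 of 35 down and 1 up (median -1.22; RNR1 -3.35 ± 0.17), while 3 were higher and 0 lower in footprints. POL30, the sliding clamp, fell in mRNA (-2.30 ± 0.28) and rose in footprints (1.33 ± 0.34). In BTT, 36 of 41 respiratory genes fell and 1 rose (median -1.01; QCR9 -2.17 ± 0.19), beside a mitochondrial share of 3.96% of mRNA reads, and 8 of 10 daughter-specific genes rose (median 1.10; DSE4 1.91 ± 0.15). These mRNA counts were the same adjusted over the list alone. The camera test with Benjamini-Hochberg adjustment gave adjusted p = 3e-06, 6.2e-05, 9.1e-07 and 0.00034 in BED, 3e-06 in BAN, and 1.7e-13 and 0.002 in BTT, in the order given, and adjusted p = 0.45, 0.45, 0.53, 0.2, 0.45, 0.46 and 0.52 with an estimated correlation.

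Among genes called in opposite directions in mRNA and footprints, 7 were so called in 5 or more isolates, in contrasts that share libraries. RIC1 ranged from 24 to 167 CPM in mRNA and from 76.7 to 1050 CPM in footprints, ALG6 from 15 to 78.3 and from 102 to 2400. PAC11 ranged from 2.59 to 30.9 and from 98.8 to 3730, with the highest footprint values in the shallow libraries of BAN and CMP. The others were CLB6, STT4, VPS33 and ECM5, with STT4 at 58.9 to 419 CPM in mRNA and 79.7 to 571 CPM in footprints. The deviation of a library correlated with coding length across genes, with Spearman's rho from -0.283 in CMP to 0.346 in BTT for mRNA and from -0.337 in BPL to 0.324 in CMP for TE; genes are not independent replicates. With these trends removed, 240 of 244 list medians called by camera in mRNA, 224 of 227 in footprints and 112 of 114 in TE kept their sign, and 26, 19 and 30 moved by over 1.5 times.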
